A study of Mus musculus with 8 samples.

How the data were processed

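GLORI libraries were made from mRNA and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The submitters' processing notes name the genome build mm39; the aligner, the site caller and their versions are not given in the sources used here. Each TBLC library has a deposited list of called sites with counts of A+G reads and of unconverted A reads, per the file headers. The deposited level is a fraction, the A reads divided by the A+G reads, and it matched that quotient in every row within 1e-05. The deposited p-value and adjusted p-value of each site are the authors' and were used only to describe and filter sites. The lists hold only sites with at least 15 A+G reads, at least 5 A reads, a level of at least 0.1 and an adjusted p under 0.005, as seen from the values. The lists also give a conversion rate per gene as a fraction and a gene coverage signal, per the file headers; how the authors computed them is not given in the sources used here, and their meaning was taken from the column names. The deposited EPSC table holds counts pooled over the libraries of each group, with every row passing those read and level minimums in at least 1 group. Its A+G columns give the coverage of a site in whole reads, and 2 columns of total coverage were not used here.

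Groups were taken from the sample titles. The level change was computed over sites called in all 4 TBLC libraries with at least 20 A+G reads in each. Changed sites and genes were tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test on methylated and unmethylated read counts with a term per library and the group effect on the methylated counts, at an adjusted p of 0.05 (Benjamini-Hochberg). Reads were summed per gene over the same sites; sites without a gene name (6.14% to 7.7% of a list) entered the site test and not the gene test. The log2 change of a site or gene is of the odds of A to G reads. Gene lists were tested with camera (correlation 0.01, and estimated) and fry of limma 3.58.1 on log2 odds with 0.5 added to A and G reads, for lists with at least 5 measured genes. Gene coverage was compared with limma on log2 values, for genes with a listed site in all 4 TBLC libraries. A median shift of 0.17 on the log2 scale, higher in siVirma, was removed first. Sites with no variance between replicates had their variance offset from 0 by limma. Intervals for medians and shares came from 1000 resamplings of genes, which cover genes and not replicates. Summaries used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9. Of 10609 gene symbols in the TBLC lists, 10448 were found in the name tables used here, whose assembly GRCm38.p6 differs from the build of the files, so only names were taken from them. No annotation of mm39 was used here, so exons, introns and UTRs are not stated and the planned comparison of transcript regions was not made.

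The planned EPSC test was edgeR on single libraries. Because the table is pooled, Fisher's exact test on pooled reads took its place, which compares the pooled libraries and not the conditions. EPSC sites took the gene name of the same site in the TBLC lists (15551 of 19342 rows) or of the gene whose listed sites span them (1392), and 2399 rows had none. The Gata6 sites had 10 to 12 reads in sgGata6, so they are given without the minimum of 20. Wilson intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

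Named genes followed a rule set before the data were examined. For TBLC these were the 8 genes with the largest fall and the 8 with the largest rise past the threshold (with at least 100 reads in every library and no overlap between groups), up to 2 genes per list with the lowest p, and the 4 sites with the largest fall and 4 with the largest rise (at least 50 reads in each library). Virma, Gata6 and the 8 genes with the most sites in neither siVirma library were always included. For EPSC they were all Gata6 sites and the 6 largest falls and 6 largest rises past the threshold, with up to 2 writer complex and primitive endoderm genes each. Some items that the rule took are not reported here. The 14 lists cover the m6A writer complex, m6A readers and erasers, primitive endoderm, naive pluripotency, primed epiblast, trophectoderm, the 2-cell stage program, FGF-ERK and Wnt signalling, Polycomb and chromatin regulators, splicing factors, the p53 pathway and apoptosis, the cell cycle, and fibroblast (feeder) markers.

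The tests were tried on simulated data. With 200 of 20414 TBLC sites simulated at 0.5 of their level, edgeR recovered 54.5% of them, with 7.63% of its calls wrong; at 0.75 it recovered 11.0%, with 15.4% of its calls wrong. In the data edgeR called 91.7% of these sites, far more than were simulated as changed, so these shares need not hold there. The simulated spread between replicates was also an assumed value. With 200 of 10185 EPSC sites at 0.5, Fisher's exact test recovered 12.0% and called 0 unchanged sites. Between replicates of a group, Fisher's exact test called 3 (siNC) and 1 (siVirma) of the 20414 sites. Alternatives covered coverage minimums, level and p filters, limma and Fisher's exact test for the site and gene tests, a replicate block, a minimum level difference of 0.1, an estimated correlation and each library left out in turn.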

Results

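N6-methyladenosine (m6A) was measured at single-base resolution by GLORI, a chemical method that converts unmethylated adenosine so that it is read as guanosine while methylated adenosine is still read as adenosine. The level at a site is the number of unconverted A reads divided by all A and G reads there. The series holds 8 mouse libraries in 4 groups of 2. TBLC cultured in MYCP medium received a control siRNA (siNC) or an siRNA against Virma (siVirma), and EPSC carried a dCas13b-FTO system with a control guide (sgCtrl) or a guide against Gata6 (sgGata6). The 4 TBLC lists hold 4764955 and 4367999 A+G reads over called sites for siNC, and 3423268 and 2655963 for siVirma. The EPSC values are pooled to 1 value per group, with 964966 A+G reads for sgCtrl and 1044927 for sgGata6 over 19342 sites, so they carry no SD. The labels do not say whether replicates came from separate cultures, and p-values then measure only the spread between these libraries, which may be technical. Coordinates are those of mm39.

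The first comparison addresses how depletion of Virma, a scaffold subunit of the m6A writer complex, changes m6A in TBLC. The gene coverage that the lists give for Virma was 40.3 and 38.2 in the siNC libraries and 24.0 and 22.8 in the siVirma libraries. Relative to the median gene, this was 0.531-fold (log2 change -0.91, SE 0.06, limma adjusted p = 8.3e-06). The number of called m6A sites was 64154 ± 3106 (SD, n = 2) in siNC and 37910 ± 4485 (SD, n = 2) in siVirma, 40.9% fewer. Both siVirma libraries lay below both siNC libraries, and the two-sided exact permutation test gave p = 0.333, the smallest that 2 against 2 libraries allow. Sites were assigned to 9682 and 9365 genes in siNC and to 8171 and 7556 in siVirma. The lists hold only called sites, so a missing site can have a lower level or lower coverage. Over the 6787 genes with a listed site in every TBLC library, coverage was not generally lower in siVirma. The median gene coverage there was 39.3 and 37.6 in siNC and 46.4 and 40.1 in siVirma. Genes missing from any list have no such value.

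**Figure D1:**
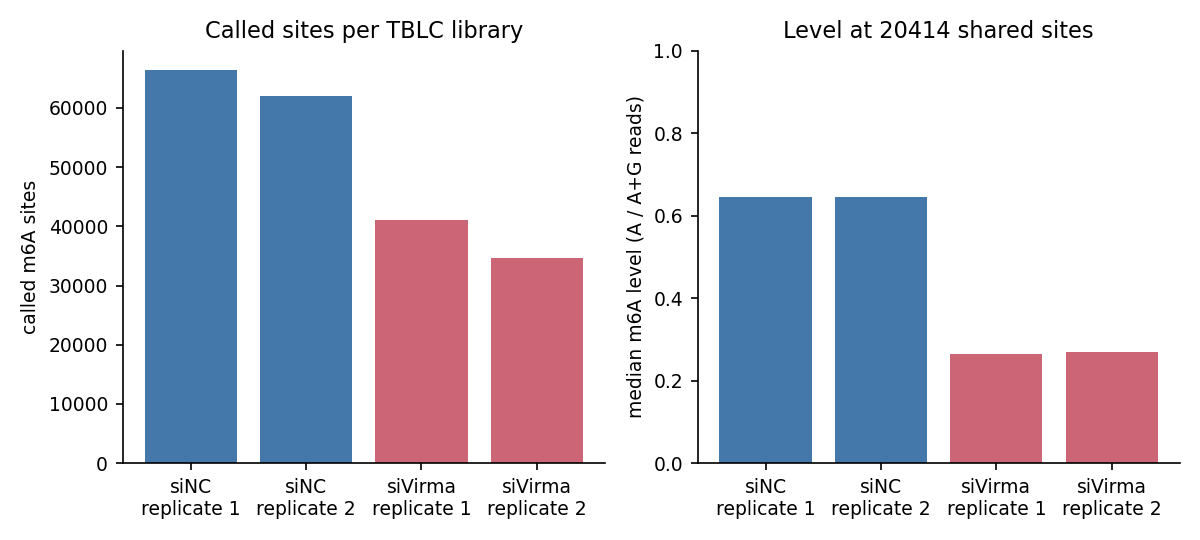
Bars give 1 TBLC library each: on the left the number of called m6A sites, on the right the median m6A level over the 20414 sites called in all 4 libraries with at least 20 reads in each. The siNC libraries have 66350 and 61957 sites and the siVirma libraries 41082 and 34739, and the median levels are 0.646 and 0.645 against 0.266 and 0.269.

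Of 49554 sites called in both siNC libraries, 23354 were called in both siVirma libraries, which is 47.1% (95% interval 46.6% to 47.7% by resampling genes). The single siVirma libraries held 59.2% and 54.9% of them, and 16405 sites (33.1%) were in neither. By comparison, 74.7% of the sites of siNC replicate 1 were in siNC replicate 2, and 80.0% the other way. Those shares are of all sites of a single siNC list, not of sites called in both. On that basis, siVirma replicates 1 and 2 held 49.9% and 45.3% of the sites of siNC replicate 1. They held 50.9% and 46.4% of those of siNC replicate 2. Retention rose with the siNC level, from 2.83% of the sites at 0.1 to 0.2 to 92.7% of those at 0.9 to 1. The calling minimums, a level of 0.1 and 5 A reads, would give such a gradient even if every level fell by the same share. In the other direction, 83.1% of the 28098 sites shared by the siVirma libraries were in both siNC lists, and 1667 of them were in neither. Among genes that still had a site in each siVirma library, Srrm2, which encodes a spliceosome-associated protein, had the most sites in neither siVirma library, 24 of 47. Dst and Fat1 each had 20, of 53 and 83 sites. Cggbp1 had 16 of 27, and C77080, Dido1, Neat1 and Nsd1 had 15 each, of 32, 46, 24 and 54. Neat1, a nuclear long noncoding RNA, had 62.5% of its sites in neither siVirma library. A ranking by number favours genes with many sites. The shares of Fat1 (24.1%), Nsd1 (27.8%) and Dido1 (32.6%) lay below the 33.1% over all sites, and those of the other genes named lay above it. The 33.1% also counts sites without a gene name and genes without a site in each siVirma library. Retention in the ranked genes alone was 50.7% against 47.1% over all sites, so 33.1% is not their own share.

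**Figure D2:**
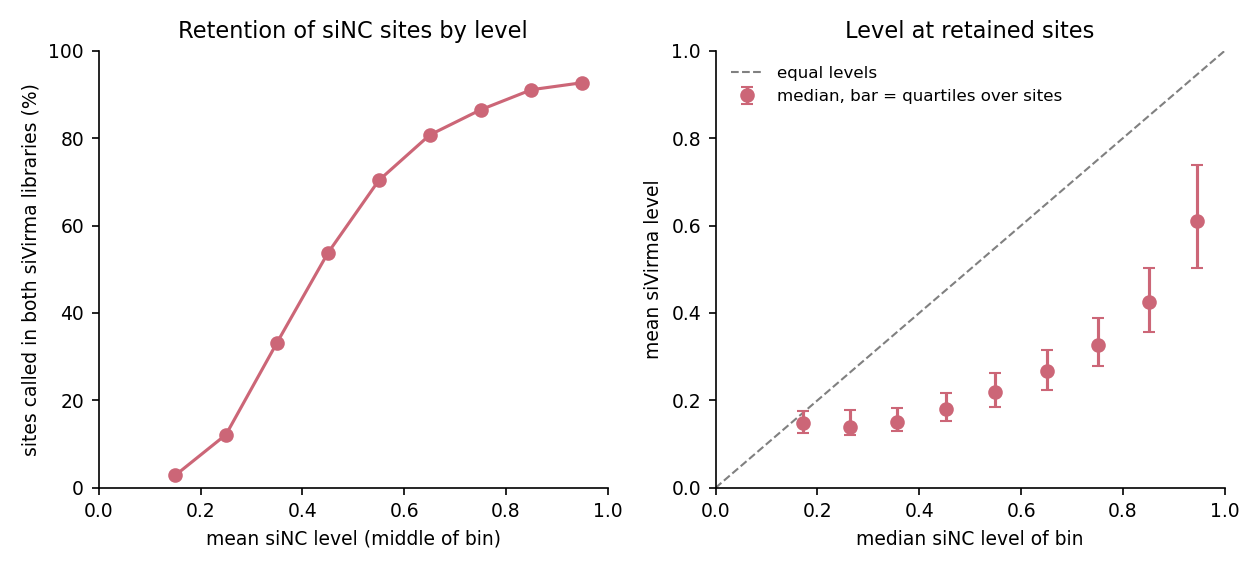
The left panel plots, for sites called in both siNC libraries and binned by mean siNC level, the percent also called in both siVirma libraries. The right panel plots the median siVirma level of the retained sites against their median siNC level, with quartiles over sites, and the bin near 0.945 in siNC lies at 0.611 in siVirma while the bin near 0.55 lies at 0.219.

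At the sites that remained measurable, the m6A level was lower in siVirma almost throughout the transcriptome. Over 20414 sites in 5642 genes, the library medians averaged 0.645 ± 0.00071 (SD, n = 2) in siNC and 0.268 ± 0.00235 (SD, n = 2) in siVirma. The median change per site was -0.328 (95% interval -0.331 to -0.325 by resampling genes), and 97.7% of the sites were lower. Over all 23354 sites called in the 4 libraries, with no minimum of reads, those at a siNC level of 0.9 to 1 kept a median of 64.6% of it and those at 0.6 to 0.7 kept 41.0%. The few that were still called at 0.1 to 0.2 kept 92.2%, and those at 0.2 to 0.3 kept 54.3%. The exact permutation test on the library medians, two-sided, gave p = 0.333, again the smallest possible. Sites that fell below the calling minimum are absent here, so the fall at low levels is understated.

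By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 18694 of the 20414 sites fell and 30 rose. Only sites called in all 4 libraries were tested, so sites missing from any list could count neither as falls nor as rises. The rises numbered 19 without siNC replicate 2, 15 without siVirma replicate 1 and 10 without siVirma replicate 2. Of 458 sites with a higher mean level in siVirma, these 30 were all that had an unadjusted p under 0.05, so the adjustment removed none of them. With 91.7% of the sites called, the adjusted threshold lay near an unadjusted p of 0.05. It therefore gave the rises little protection against chance, and how many of the 30 arose by chance was not tested. Among sites with at least 50 A+G reads in every library, the largest falls were at a site of Erf, an ETS-family repressor, on chromosome 7 at 24944100 (0.953 ± 0.00416 to 0.282 ± 0.00835, SD, n = 2), and of Otud6b on chromosome 4 at 14810193 (0.881 ± 0.0224 to 0.24 ± 0.00203). Sites of Mtcl1 on chromosome 17 at 66644450 and of Timm10b on chromosome 7 at 105290460 fell from 0.901 to 0.276 and from 0.89 to 0.271. Each of these had at least 68 A+G reads in every library. The largest rise under the same minimum was at a site of Tra2b, which encodes a splicing regulator, on chromosome 16 at 22084676, from 0.257 ± 0.00971 to 0.4 ± 0.0645 (adjusted p = 0.0059); without siVirma replicate 2 its adjusted p was 0.096. Another 3 rising sites had no gene in the lists. They lay on chromosome 4 at 33825614 (0.581 to 0.678), chromosome 3 at 45953957 (0.624 to 0.711) and chromosome 6 at 140265440 (0.422 to 0.503). Their adjusted p of 0.025 to 0.0413 did not hold with single libraries left out. The chromosome 4 site had 0.196 without siNC replicate 1 and 0.361 without siVirma replicate 2, where its change of 0.097 was 0.0519. The chromosome 3 site had 0.143 without siNC replicate 2, 0.121 without siVirma replicate 1 and 0.105 without siVirma replicate 2. The chromosome 6 site had 0.213 without siNC replicate 1, 0.075 without siNC replicate 2 and 0.715 without siVirma replicate 1; its change of 0.081 was 0.0194 there and 0.143 without siVirma replicate 2. By limma on logit levels the adjusted p of these 3 sites was 0.149, 0.138 and 0.264.

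Summed per gene, 5294 of 5642 genes fell and 10 rose; the rises numbered 4 without siNC replicate 2 and 5 without siVirma replicate 2. Of 125 genes with a higher mean level, these 10 were likewise all that had an unadjusted p under 0.05. With 94.0% of the genes called, the adjustment gave these rises little protection against chance too. The median gene kept 44.9% of its siNC level, with quartiles of 38.3% and 53.5%. The groups did not overlap in 96.0% of the genes, against 33.3% by chance. Timm10b, which encodes a mitochondrial import subunit, fell from 0.89 ± 0.0123 to 0.271 ± 0.0198 (SD, n = 2; log2 odds -4.44, SE 0.25, edgeR adjusted p = 5.04e-21). Polr2h, which encodes an RNA polymerase subunit, fell from 0.902 ± 0.00436 to 0.319 ± 0.00459. Ctsc, which encodes a lysosomal protease, fell from 0.863 ± 0.0269 to 0.299 ± 0.0389. Rsl24d1, Med28 and Ube2e3 fell from 0.937 to 0.376, 0.849 to 0.29 and 0.887 to 0.33. The predicted genes Gm12751 and Gm44163 fell from 0.955 to 0.385 and 0.92 to 0.356, and reads of such genes can be shared with related copies.

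The genes that rose with no overlap between groups and at least 100 reads in every library were the tRNA genes Trnak-cuu and n-TStga1 and the pseudogene Rps12-ps19. Trnak-cuu rose from 0.765 ± 0.021 to 0.843 ± 0.0465 and n-TStga1 from 0.952 ± 0.00405 to 0.978 ± 0.00212 (SD, n = 2). Rps12-ps19 rose from 0.31 ± 0.0145 to 0.369 ± 0.0414. Their edgeR adjusted p values were 0.0259, 0.0239 and 0.0331. These calls ended without single libraries: n-TStga1 without any 1 of the 4 (adjusted p 0.0516 to 0.0898), Trnak-cuu without siNC replicate 2 (0.113) or siVirma replicate 2 (0.287), and Rps12-ps19 without siNC replicate 1 (0.153) or siVirma replicate 2 (0.331). Without siVirma replicate 2 the change of 0.0781 for Trnak-cuu was 0.0452, and that of 0.0595 for Rps12-ps19 was 0.0302. By limma on logit levels the adjusted p was 0.0667 for Trnak-cuu and 0.133 for Rps12-ps19, and that of Trnak-cuu was 0.274 by edgeR with a minimum of 50 reads, where 1 of its 2 sites remained and the change was 0.0128. Copies of tRNA and ribosomal protein genes can share reads, and tRNA sites could carry other modifications that conversion leaves alone.

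Virma itself had 34 and 30 called sites in siNC and 14 and 7 in siVirma, between 11513308 and 11550481 on chromosome 4. Its single site with at least 20 reads in every library fell from 0.804 ± 0.0443 to 0.641 ± 0.0233 (SD, n = 2; edgeR adjusted p = 0.0171), a remaining share of 79.8%. The siVirma reads at this site numbered 38 and 24. The adjusted p was 0.0948 without siNC replicate 2 and 0.27 without siVirma replicate 1, where the change of -0.163 was -0.0779 with 2 sites reaching the minimum. Over the 6 Virma sites called in all 4 libraries, with no further minimum, the level was 0.746 ± 0.046 and 0.617 ± 0.037 (edgeR adjusted p = 0.000268).

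Genes of the 14 lists fixed before the data were examined fell along with the rest of the transcriptome. Of 178 list genes tested, 169 fell and 0 rose by edgeR, with 0 higher at an unadjusted p under 0.05 by edgeR, limma or the pooled Fisher's exact test. Each list fell as a set (fry adjusted p 0.00025 to 0.00376), which is 14 of 14 lists. Against the other genes, camera called 0 of 14 lists, and 0 at an unadjusted p under 0.05 (adjusted p = 0.981 for every list, and adjusted p = 0.986 with an estimated correlation). The counts adjusted over the list alone equalled those over all genes for each list. In the m6A writer complex, 7 of 7 tested genes fell. Wtap, an adaptor of the complex, fell from 0.706 ± 0.0432 to 0.171 ± 0.00948 and Rbm15b from 0.631 ± 0.0244 to 0.371 ± 0.00155 (SD, n = 2). Among m6A readers and erasers, 6 of 7 fell, including the cytoplasmic readers Ythdf1 (0.638 to 0.34) and Ythdf3 (0.67 to 0.43). In the primitive endoderm list, 12 of 13 fell, including Nid2, which encodes a basement membrane protein, from 0.479 ± 0.00259 to 0.183 ± 0.00112. All 22 tested naive pluripotency genes fell, including Zfp42 (0.574 to 0.312) and the zinc finger gene Sall4 (0.748 to 0.354), which is also in the primitive endoderm list.

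All 22 tested FGF-ERK signalling genes fell, including the ligand Fgf4 (0.622 ± 0.0126 to 0.243 ± 0.00456, SD, n = 2) and the feedback inhibitor Spry2 (0.807 ± 0.0171 to 0.486 ± 0.0172). All 14 Wnt signalling genes fell, including Ctnnb1, which encodes beta-catenin (0.583 to 0.243), and the receptor gene Fzd5 (0.624 to 0.406). Among Polycomb and chromatin regulators 22 of 23 fell, including the histone methyltransferase gene Setdb1 (0.727 to 0.34) and the histone demethylase gene Kdm5b (0.639 to 0.311). Of the splicing factors 17 of 18 fell, including Srrm2 (0.596 to 0.275) and Sf3b3 (0.554 to 0.192). Of the cell cycle genes 12 of 13 fell, including the kinase gene Wee1 (0.778 to 0.231) and the cyclin gene Ccne1 (0.686 to 0.323). In the p53 pathway and apoptosis list 14 of 16 fell, including Sesn2 (0.797 to 0.393) and the anti-apoptotic gene Mcl1 (0.554 to 0.265). In the primed epiblast list 5 of 6 fell, including Nodal (0.723 to 0.452). In the trophectoderm list 4 of 5 fell, including Tead4 (0.908 ± 0.019 to 0.47 ± 0.127) and Id2 (0.951 to 0.454). The Tead4 change of -0.438 at 1 site was -0.239 without siVirma replicate 2, where 3 sites reached the minimum. All 8 tested genes of the 2-cell stage program fell, including Eif1a (0.684 to 0.4) and Dppa2 (0.511 to 0.19).

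All 8 tested fibroblast (feeder) markers fell in level, including Col6a2 (0.715 to 0.322) and Twist2 (0.552 to 0.115). Their gene coverage moved with the groups as well: 8 of 11 had higher coverage in siVirma and 0 lower by limma on centred log2 coverage (0 lower at an unadjusted p under 0.05), with Col6a1 at 2.16-fold and Col1a2 at 1.52-fold. The list's camera adjusted p was 9.21e-09, and the adjusted p was 0.363 with an estimated correlation. Coverage of the 2-cell stage program was lower for 5 of 10 genes and higher for 0 by limma (0 at an unadjusted p under 0.05), with Dppa2 at 0.745-fold (camera adjusted p = 0.0152, and adjusted p = 0.664 with an estimated correlation). Only genes with a listed site in every library had coverage values. These were 11 of the 20 fibroblast markers and 10 of the 30 genes of the 2-cell stage program.

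**Figure D3:**
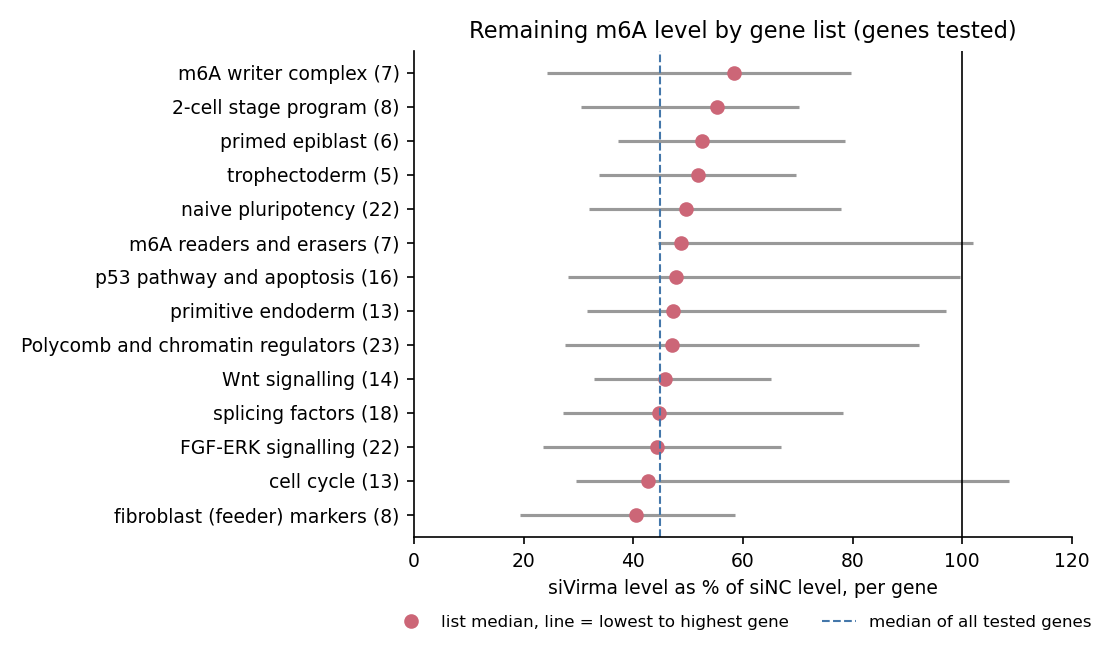
Each row is a fixed gene list with the number of genes tested; the point is the list's median siVirma level as a percent of the siNC level, the line runs from its lowest to its highest gene, and the dashed line is the median of all tested genes, 44.9%. List medians run from 40.5% for fibroblast (feeder) markers to 58.4% for the m6A writer complex.

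The second experiment asks whether a Gata6 guide with dCas13b-FTO, an inactive Cas13b fused to the m6A demethylase FTO, lowers m6A on Gata6, a transcription factor gene of the primitive endoderm. The pooled EPSC table lists 3 Gata6 sites on the plus strand of chromosome 18. At 11085019 the level was 0.696 in sgCtrl (16 of 23 reads) and 0.364 in sgGata6 (4 of 11 reads). At 11085025 it was 0.889 (24 of 27) and 0.6 (6 of 10), and at 11085029 it was 0.5 (14 of 28) and 0.333 (4 of 12). Summed over the 3 sites, the level was 0.692 in sgCtrl (95% Wilson interval 0.583 to 0.784) and 0.424 in sgGata6 (0.272 to 0.592), with a two-sided Fisher's exact p = 0.0107. No single site passed (Fisher's exact p = 0.135, 0.0688 and 0.49). Adjusted over the Gata6 sites alone, these Fisher's exact p-values were 0.202, 0.202 and 0.49. Adjusted over all sites, none was below 0.68. These tests compare the pooled reads, not the conditions; the sites lie within 10 nt and can share reads, and the sgGata6 coverage is below the planned minimum of 20 reads.

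Summed over these sites, Gata6 coverage was 78 reads in sgCtrl and 33 in sgGata6, a ratio of 0.423. Reads shared between the sites count more than once in these sums. The median ratio was 1.13 over 46 other sets of 3 neighbouring sites within 30 nt with 15 to 40 sgCtrl reads each. Of these sets, which can share sites, 0 had a ratio as low. Of 1818 single sites compared, 3.14% had a ratio as low (median 1.12). In level, 0 of the 46 sets fell as much as Gata6, and their median difference was -0.0473. Of these sets, 16 had a level of at least 0.5, and 0 of those fell as much. The sets are pooled as well and carry no spread between replicates. In TBLC the same 3 Gata6 sites fell together from 0.7 ± 0.00313 in siNC to 0.332 ± 0.0157 in siVirma (SD, n = 2; log2 odds -2.22, SE 0.22, edgeR adjusted p = 1.22e-12). As in EPSC, these sites can share reads, which the sum counts more than once, so its SE and p may be too small. Singly, 11085019 fell from 0.852 to 0.274 and 11085025 from 0.805 to 0.393, while 11085029 did not pass (0.445 and 0.328, edgeR adjusted p = 0.061). Gata6 gene coverage in siVirma was 0.854-fold that in siNC relative to the median gene (limma adjusted p = 0.0102).

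**Figure D4:**
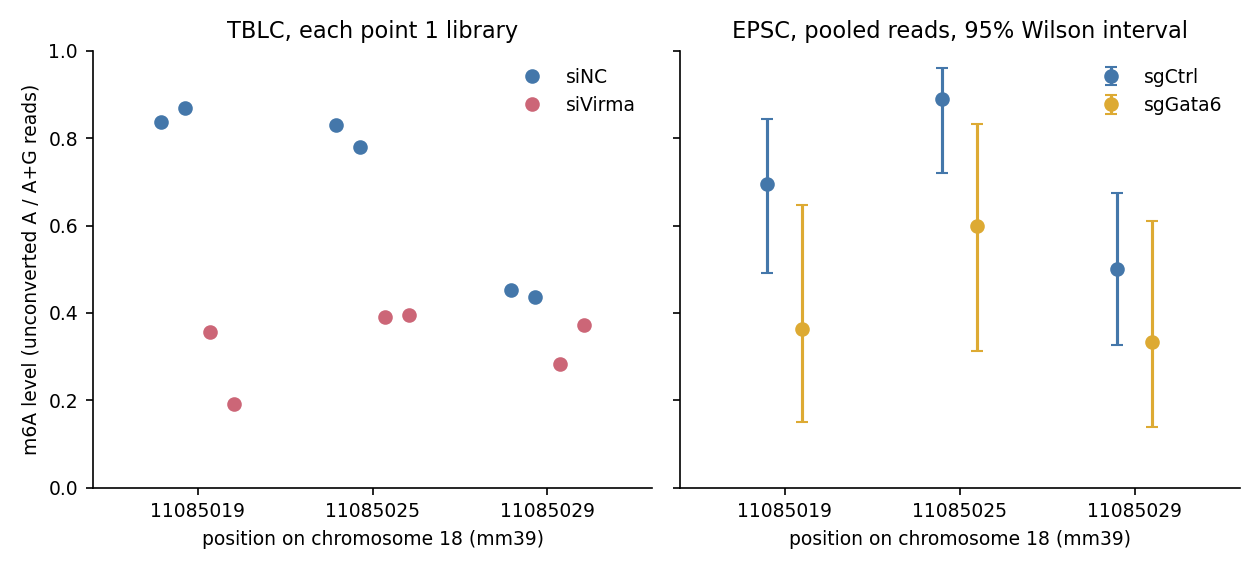
The m6A level (unconverted A reads over A+G reads) at the 3 Gata6 sites on chromosome 18, with 1 point per library in TBLC on the left and the pooled reads of each EPSC group with 95% Wilson intervals on the right. At 11085019 the EPSC level is 0.696 in sgCtrl and 0.364 in sgGata6, and the intervals of the EPSC groups overlap at each site.

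Outside Gata6, over 10185 sites with at least 20 reads in both groups, the median level was 0.222 in sgCtrl and 0.224 in sgGata6, and the median difference was -0.00906. At an unadjusted p under 0.05, 930 sites were lower and 267 higher in sgGata6, which is 11.8% of the sites. Fisher's exact test called 26 sites lower and 2 higher in sgGata6 after Benjamini-Hochberg adjustment. The largest called falls with a gene name were at a site of Ncl, which encodes nucleolin, on chromosome 1 at 86284027 (0.176 to 0.026), of Gm26917 on chromosome 17 at 40159074 (0.673 to 0.552) and of Gm6368 on chromosome X at 140764413 (0.123 to 0.00518). Falls without a gene name were on chromosome 2 at 166838073 (0.45 to 0.0625) and at 130723215 (0.143 to 0, with 0 of 98 reads, where a limit of 3 reads allows a level of up to 0.0306 and the 95% Wilson upper bound is 0.0377), and on chromosome 4 at 126573594 (0.138 to 0.0242). The 2 rises were at a site of Sfpq, which encodes a splicing factor, on chromosome 4 at 126926430 (0.128 to 0.405), and on chromosome X at 21546813 (0.186 to 0.204). No site of the m6A writer complex (5 sites tested) or the primitive endoderm list (71 sites) was called, nor any site of the other lists. With 28 of 10185 sites called in all, 0 calls among so few sites says little about these lists. Every listed site had to pass the calling minimum in at least 1 group, which favours differences by chance, and requiring 50 reads changed the count from 28 to 85, of which 77 were lower and 8 higher.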

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

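The tests of conversion and of Virma depletion in this part were chosen after the result was seen, and the test of coverage before. The conversion rate per gene, a column outside the main measurement, was higher in siVirma than in the siNC controls by a median of 0.651 percentage points over 6787 genes, with library medians of 98.1% and 98.1% in siNC and 98.8% and 98.8% in siVirma. The rise was 0.386 points in 925 genes with 1 site and 0.987 points in 462 genes with over 16 sites, and 0.242 points in 51 tRNA genes.

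The pattern weighed is the fall of the m6A level in siVirma, a median of -0.328 per site. More complete conversion would lower other incompletely converted adenosines too, but 62 sites in tRNA genes and on the mitochondrial chromosome had a median change of 0.00879 (quartiles -0.0114 and 0.0374); some of these could carry other modifications that conversion leaves alone, and the rise in conversion of 0.651 points is itself far below the fall. Lower coverage is argued against by the 16535 sites with siVirma coverage at least that in siNC, whose median change was -0.336. Depletion of Virma needs low Virma coverage, and the higher of its percentiles among genes in the siVirma libraries was 0.103. As a hypothesis, loss of the writer subunit may account for the fall, and the rise in conversion may partly be the same loss counted per gene; effects of the siRNA on other genes were not tested.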

How the results depend on the processing

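The runs without tRNA and mitochondrial sites and with each Gata6 site alone were chosen after seeing the data. The ratio of called sites (siVirma to siNC, 0.591) was 0.666 with at least 50 reads and 0.447 with a level of at least 0.3, and ranged from 0.541 to 0.64 with each library left out. Retention (47.1%) was 72.2% at a siNC level of at least 0.3 and 50.7% in genes with a site in each siVirma library. It ranged from 38.3% to 59.2% with a library left out, since a site then has to be called in only 1 library of that group. The median level change (-0.328) was -0.344 at a siNC level of at least 0.3 and -0.264 as a read-weighted level, and -0.327 to -0.299 with a library left out; the cause was not tested. Changed sites numbered 8514 and changed genes 3111 with a minimum of 50 reads, where only 9010 sites and 3275 genes were tested; all other settings stayed within 1.5 times. Of these calls, 10 sites and 3 genes rose with 50 reads and 15 and 4 with a level difference of at least 0.1, against 30 and 10. Replicate numbers did not pair the TBLC samples (correlation of deviations 0.0079), and with a replicate block 18723 sites and 5303 genes changed, against 18724 and 5304. No paired analysis was possible for EPSC because its values are pooled; edgeR, limma, the block and the runs without a library were not run there, nor was the comparison of transcript regions with its alternatives. EPSC calls numbered 85 with 50 reads and 11 with a level difference of at least 0.1, against 28; the first tests fewer and deeper sites. The EPSC Gata6 difference of -0.268 was -0.332, -0.289 and -0.167 at the single sites, none past the threshold, and -0.263 as an unweighted mean. The single sites have fewer reads, and the sum can count shared reads more than once. Which of these sets the sum apart was not tested. No minimum is the setting already used for Gata6. Camera called 0 of 14 lists, and 0 in each alternative (9 lists with 50 reads), also at an unadjusted p under 0.05, while fry called 14 of 14. Among the 48 genes and sites that the naming rule took, 402 of 427 alternative values kept their direction and side of the threshold, and 25, in 8 of them, lost the call; none reversed. The Gata6 result is limited by pooling and by the 33 sgGata6 reads summed over 3 sites, which can include the same reads more than once.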

Other observations

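Gene coverage, compared with limma over 6787 genes, was higher in siVirma for 815 and lower for 1005. Only genes with a listed site in every TBLC library had values. A gene that dropped out of any list could not be counted, so falls may be missed. The names here were chosen after their values were seen. Wtap, whose m6A level kept 24.2% of its siNC value, had coverage 1.89-fold that in siNC. Hes6 stood at 2.76-fold, Gpc1 at 2.25-fold and Sp5, a Wnt-responsive transcription factor gene, at 2.18-fold. Ptgs2, which encodes a prostaglandin synthase, stood at 0.448-fold, the long noncoding RNA Neat1 at 0.477-fold and Ccn1 at 0.631-fold. In the naive pluripotency list 8 of 22 genes were lower and 3 higher (camera adjusted p = 0.345), with Nr0b1 at 0.794-fold, Tet2 at 0.697-fold and Mycn at 1.44-fold. Mat2a, known as a target of the separate methyltransferase METTL16, kept 94.4% of its level over 5 sites (0.732 ± 0.00357 and 0.691 ± 0.00879, SD, n = 2), a fall that passed the test (edgeR adjusted p = 0.0104).

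The tests on Virma below were chosen after the result was seen, and those on intronless genes before. The 6 Virma sites called in all 4 libraries kept on average 82.6% of their siNC level, against a median of 55.7% in 10000 sets of sites matched on siNC level and siVirma coverage. Level and coverage are argued against as the reason, since Virma lay at percentile 99.99 of those sets, and 0 of 194 comparable genes kept as much. Those 194 do not cover every gene, and Mat2a, given above, kept 94.4% of its level over 5 sites. Virma mRNA remaining from cells that escaped the siRNA is a candidate explanation that stays open, as the lower of the percentiles in the single siVirma libraries, 99.93, only restates the pattern. Only 6 sites of 1 gene carry this, and a direct effect on the cleaved mRNA was not tested.

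Looking at genes that kept most of their level prompted a list of 45 other genes taken, from general knowledge and with no annotation used here, to lack introns; it was written before their values were seen. Of these, 17 had values, 16 of them above sites of like siNC level and coverage, against 45.0% of other genes. Their median excess was 8.72 percentage points of remaining share, at percentile 99.98 of 10000 random lists matched on coverage. By the remaining share itself, not set against sites of like level, the list lay at percentile 99.69. The position above the random lists at 99.98 with that matching argues against site level and coverage as the whole reason. As a hypothesis, m6A in intronless genes may depend less on Virma; site position within transcripts and mRNA turnover were not tested.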
